A study of Hordeum vulgare with 4 samples.

How the data were processed

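RNA sequencing was analysed for 4 barley callus libraries, 2 of cultivar GP and 2 of cultivar D91. Per the labels' protocols, total RNA was purified on columns with DNase digestion, 1.5 µg went into each library, and the libraries were made with a SMARTER mRNA kit. The submitters' processing notes name STAR, RSEM and DESeq2 without versions. The identifiers begin with TRINITY_GG, the prefix that Trinity gives to genome-guided assemblies. The genome build, the filters and whether all libraries were pooled for the assembly are not given in the sources used here.

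The 4 deposited tables hold isoforms and genes, each as counts and as TMM-scaled expression. The authors' isoform table holds expected counts, which are not whole where isoforms share reads. The authors' TMM tables hold an expression signal, TPM multiplied by one factor per library. The deposited gene table that is named as counts also holds such a signal and not reads per gene. In each library its values were in a fixed ratio to the summed isoform TPM of the gene (coefficient of variation of the ratio at most 0.00185% over genes above 100), while their ratio to the summed isoform counts varied by 83.4% to 91.8%. Each column summed to the library's total of isoform counts. Its values are therefore gene TPM scaled to the library total. Gene counts were instead obtained by summing the isoform expected counts of each gene and rounding to whole numbers, and the deposited gene table was kept as an alternative. No column of an unmapped sample was present (0).

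Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a model with cultivar only, glmQLFit and glmQLFTest, and an adjusted p under 0.05. Fold changes are GP minus D91 on the log2 scale, and standard errors are the absolute fold change divided by the square root of F. Isoform counts were tested in the same way. Log2 CPM (counts scaled to library size) used a prior count of 2. Genes with no counts in one cultivar needed 0 in both of its libraries and at least 10 in both of the other, and their folds are bounds against 3 counts per library. With 2 libraries against 2, a permutation test of one value cannot go below p = 0.333, so single values have no such test. On simulated data drawn from the means and dispersions of the 18035 genes, with 200 genes changed, the gene test recovered 74% of 100 genes changed 4-fold and 5% of 100 genes changed 2-fold, and also called 17 of the 17835 unchanged genes. With no gene changed it made 8 calls. The data gave calls at 19.2% of genes, so the adjusted p was stricter in the simulation. Both cultivars were also drawn with the same dispersion per gene. These shares and false calls therefore do not measure how the test performed on the data.

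Before the data were examined, the main tests, alternatives, 23 gene lists defined by product names (photosynthesis, plastid, hormones, regeneration, cell cycle, stress, tissue markers and others) and the rule for named genes were fixed. The comparison of direction between abundance classes and the shuffle of isoform directions were not among them. The files do not pair the identifiers with gene names, and 0 of the 61598 gene identifiers matched the 58438 entries of the reference table. The lists, the share of plastid genes, the leaving out of organelle genes and the placement along chromosomes therefore gave no values. The rule for named genes gave 2 identifiers per direction, those with the largest fold among genes past the threshold with at least 10 counts in every library. Its parts on gene lists and on genes without counts would have added names, and those identifiers are not printed because they name no known gene.

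Replicate numbers are shared between cultivars, but no label ties them to a culture or day. With 2 pairs, the deviations of same-numbered libraries from their cultivar means correlated at r = 0.03 across genes, so the numbers were not treated as pairs. No label gives a batch. Of the tested genes, 555 had the same rounded counts in all 4 libraries as another tested gene at a different locus, which reads shared between near-identical copies would give. Low counts may also coincide, and how often was not estimated. Of the 555 genes, 170 were among the genes called, 94 beyond 1 per set. These genes are uncertain, and none of the named genes (0) was among them. Alternatives were RLE size factors, library totals, other filters, DESeq2 1.42.0, limma 3.58.1 on counts (voom) and on log2 of the deposited signal with pseudocounts of 1 and 0.1, a replicate block, a test against a 2-fold change, and leaving out each library. Alternatives added after seeing the data were the deposited gene table in edgeR and DESeq2, limma on the deposited signal of all genes that passed the filter in that table, counts summed per locus (the number after TRINITY_GG), D91 replicate 2 thinned to the total of replicate 1, and removal of a smooth trend with relative transcript length. Relative length was taken as isoform count divided by isoform signal, scaled to the median isoform. For the genes without counts, summing per locus was first judged over all 349 loci (96.3% stayed past the threshold in the same direction), then limited to loci with another tested gene, since the others cannot change much. A test of the summed CPM at the 315 other loci (lower in the cultivar without counts by over 4-fold at 99.7%) was also set aside, because the choice of these loci nearly fixes its outcome. The 273 loci with no count of any gene in the cultivar without counts were counted only among these 315. Their share is therefore not read as a result.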

Results

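Messenger RNA libraries from barley (Hordeum vulgare) callus, the undifferentiated tissue from which plants are regenerated in culture, were compared between 2 cultivars. These were Golden Promise (GP), a cultivar widely used for barley transformation, and DWR91 (D91). All 4 calli were sampled at 31 days, after 28 days of induction in the dark and 3 days of indirect light on the second medium. The cultivars were contrasted for their capacity to regenerate in vitro, and the comparison asked which transcripts differed between their calli. Each cultivar had 2 libraries, D91 replicates 1 and 2 and GP replicates 1 and 2. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

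The estimated counts summed to 1743621 in D91 replicate 1, 3443040 in D91 replicate 2, 1825505 in GP replicate 1 and 1737140 in GP replicate 2. They were assigned to 75397 isoforms of 61598 genes at 34032 loci of a transcript assembly. At least 1 count was found for 40561 and 48245 genes in the D91 libraries and for 46417 and 45459 genes in the GP libraries. The 100 most abundant genes took between 18.8% and 19.8% of the counts in every library. The most abundant gene took 1.90% and 1.17% of the counts in D91 and 2.36% and 2.59% in GP. The assembled genes carry no names, so no gene could be assigned to chloroplast, hormone or regeneration functions, and groups of genes are described here by their behaviour.

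The libraries separated by cultivar. Counts were scaled to library size as CPM. The first principal component of log2 CPM held 78.0% of the variance over 18035 tested genes, with both GP libraries at 79.2 and 81.3 and both D91 libraries at -83.1 and -77.3. Across genes, which are not independent replicates, Pearson's r was 0.92 between the D91 libraries and 0.95 between the GP libraries, and lay between 0.72 and 0.73 for the 4 pairs of a GP and a D91 library. Between 25.2% and 27.9% of genes differed over 2-fold in a pair from different cultivars. The D91 replicates differed over 2-fold for 10.4% of genes (1881) and the GP replicates for 4.60% (830), so the D91 replicates lay further apart.

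By assigned counts, callus of the 2 cultivars differed in 3465 of the 18035 tested genes, or 19.2%. Of these, 1652 were higher in GP and 1813 were higher in D91 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median absolute log2 fold change of these genes was 1.77, and it was 1.63 over the 3097 of them with counts in both cultivars. With genes lacking counts in one cultivar placed at their lower bound, the median of all 3465 stayed at 1.77, because every bound lay above it. With those genes at their bound, 2904 genes (83.8%) differed over 2-fold and 1478 (42.7%) over 4-fold. The genes higher in GP took 10.3% ± 0.299 (SD, n = 2) of the counts in GP and 2.95% ± 0.0509 (SD, n = 2) in D91. The genes higher in D91 took 20.04% ± 0.111 (SD, n = 2) of the counts in D91 and 7.90% ± 0.283 (SD, n = 2) in GP. These genes were chosen on the same libraries, so the shares describe the size of the difference and are not a separate test of it. Alleles assembled apart, or reads of a cultivar that failed to be assigned, may also give such differences, also at the genes named below. This was examined only for the genes without counts in one cultivar.

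**Figure D1:**
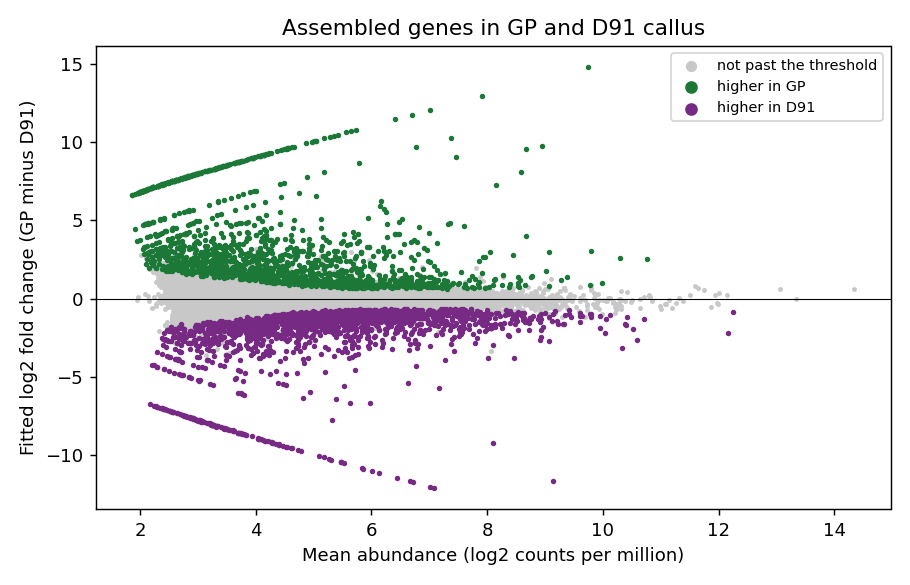
Fitted log2 fold change (GP minus D91) of 18035 assembled genes against their mean abundance in log2 CPM, with 1652 genes higher in GP in green, 1813 higher in D91 in purple and the other genes in grey. The straight bands at the top and bottom are genes without counts in one cultivar, whose fitted folds depend on the prior count and are not bounds.

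The count of genes depended on the method, the genes entered and the libraries included. On all 4 libraries DESeq2 called 1822 genes (763 higher in GP and 1059 in D91), and edgeR without a filter on low counts 2004 (734 and 1270). DESeq2 started from all genes with a count and kept 25080 after its own filtering, so its set was unlike the 18035 genes of the main test. On genes with at least 10 counts in every library, edgeR called 2198 (971 and 1227). Limma called 2043 (835 and 1208) on the deposited TMM-scaled values with a pseudocount of 0.1. Against a 2-fold change 1149 genes passed in edgeR (648 and 501). The deposited gene table, which holds scaled values and not reads, gave 0 genes in edgeR and 1607 in DESeq2 (866 and 741). With summed counts in edgeR, the count was 6902 without D91 replicate 1 and 6149 without D91 replicate 2, but 972 without GP replicate 1 and 700 without GP replicate 2. In these fits the lone library of a cultivar is assumed to vary like the pair of the other cultivar. Under library totals in place of TMM scaling, the median log2 fold change of all tested genes moved from 0.01 to 0.12, and the split became 1998 genes higher in GP and 1491 higher in D91. Directions are given relative to the TMM scale.

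Among the genes that differed, 2044 had at least 10 counts in every library, 790 of them higher in GP and 1254 higher in D91, with a median absolute log2 fold change of 1.25. The 2 genes per direction with the largest fold in this group are given for their size, since their choice after the test largely fixes that they exceed the spread between replicates. TRINITY_GG_25823_c0_g1 reached 172 ± 49.1 CPM in GP and 6.42 ± 4.24 in D91 (SD, n = 2 each), a log2 fold change of 4.90 with a standard error of 0.45 (edgeR adjusted p = 0.00249). TRINITY_GG_25108_c0_g1 reached 317 ± 163 CPM in GP and 12.5 ± 10.7 in D91 (SD, n = 2 each), a log2 fold change of 4.81 with a standard error of 0.66 (edgeR adjusted p = 0.00663). In the other direction, TRINITY_GG_1371_c0_g1 stood at 203 ± 88.6 CPM in D91 and 10.1 ± 5.29 in GP (SD, n = 2 each), a log2 fold change of -4.32 with a standard error of 0.46 (edgeR adjusted p = 0.00367). TRINITY_GG_33644_c0_g1 stood at 287 ± 57.4 CPM in D91 and 18.3 ± 7.02 in GP (SD, n = 2 each), a log2 fold change of -3.96 with a standard error of 0.32 (edgeR adjusted p = 0.00201). Single libraries moved the fold of 3 of them by over 1.5 times. The log2 fold change of TRINITY_GG_25823_c0_g1 was 5.59 without D91 replicate 1 and 4.14 without D91 replicate 2. That of TRINITY_GG_25108_c0_g1 was 5.94 without D91 replicate 1, 3.94 without D91 replicate 2 and 4.11 without GP replicate 1. That of TRINITY_GG_1371_c0_g1 was -4.997 without GP replicate 1.

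**Figure D2:**
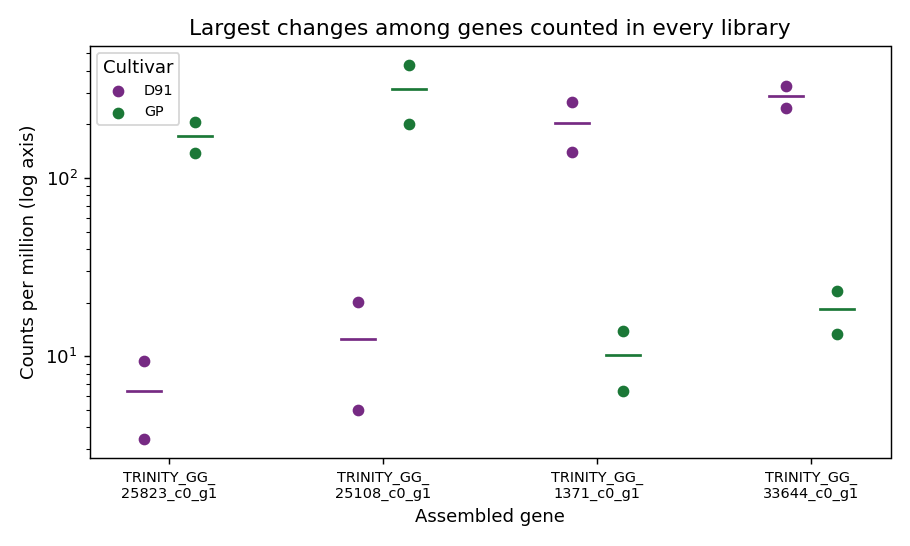
CPM (log axis) of the 2 genes per direction with the largest fold among genes with at least 10 counts in every library. Points are libraries, 2 per cultivar, and lines are means. The genes were chosen for their fold among genes past the threshold, so the gap between GP and D91 is not a separate test.

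The direction of the difference moved with abundance. Tested genes were divided into 5 equal classes by mean abundance. In the least abundant class (3.63 to 9.74 CPM), 715 genes differed and 66.2% of them were higher in GP. In the most abundant class (59.7 CPM and above), 848 genes differed and 30.8% of them were higher in GP. The shares differed between these classes across genes, which are not independent (Fisher's exact test, two-sided, p = 5.03e-45). This comparison was not fixed in advance. The shares did not keep this order when either GP library was left out. Without GP replicate 1 the shares were 37.5% and 39.4% (p = 0.811, Fisher's exact test), and without GP replicate 2 they were 42.1% and 52.0% (p = 0.173, Fisher's exact test). These fits called 120 and 193 genes in the least and most abundant class without GP replicate 1, and 95 and 125 without GP replicate 2.

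Some genes had counts in one cultivar only. Of the genes that differed, 225 had no count in either D91 library and at least 10 in both GP libraries, and 143 had no count in either GP library and at least 10 in both D91 libraries. They were 13.6% of the genes higher in GP and 7.89% of those higher in D91. Against a floor of 3 counts per library, the 225 genes were at least 4.55-fold to at least 1312-fold higher in GP, with a median bound of 10.2. The 143 genes were at least 3.60-fold to at least 147-fold higher in D91, with a median bound of 9.41. Most of these genes were of low abundance, with medians of 13.2 and 15.9 CPM, and 14 and 15 of them had at least 100 counts in both libraries of the cultivar with counts. The floor of 3 counts equalled 1.72 and 0.871 CPM in the D91 libraries and 1.64 and 1.73 in the GP libraries. Of these 368 genes, 71 had the same counts in all 4 libraries as another tested gene at a different locus and are uncertain for that reason. The floor covers counting error only, and reads are not independent molecules. These genes also had to pass the test, so their number moves with the number of calls. With D91 replicate 2 thinned to the total of replicate 1, 250 genes lacked counts in D91 and 144 in GP. The number without counts in D91 was 422 when D91 replicate 2, the deepest library, was left out, and 120 and 109 without GP replicate 1 and GP replicate 2.

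Isoforms were compared in the same way. Of 20632 tested isoforms, 954 were higher in GP and 1006 were higher in D91 (edgeR quasi-likelihood test, adjusted p under 0.05). For 1605 of these 1960 isoforms the gene also differed, and for 355 it did not pass the test. In the assembly 53904 of 61598 genes had 1 isoform, where both tests used the same counts. This overlap is therefore partly built in and is not separate support. Of the 1960 isoforms, 473 had no counts in D91 and 328 had none in GP, with at least 10 in both libraries of the other cultivar. Among all isoforms 549 and 466 had this pattern, and the genes of 612 of these had counts in both cultivars. Whether alleles assembled apart, as considered below for genes, account for such isoforms was not tested. Of 1761 genes with an isoform that differed, 117 had isoforms in both directions, and 33 of the 117 differed in total counts. In 104 genes, 1 isoform had no counts in D91 and another had no counts in GP, each with at least 10 counts in both libraries of the other cultivar. With directions shuffled among such isoforms the mean was 73.4 genes and the highest of 1000 shuffles was 93 (permutation p = 0.001, one-sided, the smallest these shuffles can give). The total counts of these 104 genes had a median absolute log2 fold change of 0.58, and 24 of them passed the gene-level test. Estimated counts of isoforms share reads, so their levels are less certain than those of genes. Reads not given to an isoform may go to another of the same gene, which ties their directions. The shuffle treats directions as free, so its p-value does not show an excess beyond this tie. The number of isoforms changed with the libraries included: no isoform passed in edgeR without GP replicate 1 (3835 at an unadjusted p under 0.05) or without GP replicate 2 (3314), while 2950 passed without D91 replicate 1 and 2839 without D91 replicate 2.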

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

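Of the 3465 genes, 2 reversed in the deposited tables and 3 with the length trend removed; leaving out a library keeps 3 of the libraries the genes were called on, and other scalings and filters hardly move a fold, so neither tests their direction. The count stayed within 1.5 times under RLE size factors (3469), library totals (3489; 1998 higher in GP and 1491 in D91), limma-voom (3386), thinning (3426), length correction (3173) and locus sums (3527). The replicate block gave 3040 genes and, for isoforms, 0 in edgeR (5000 at an unadjusted p under 0.05, smallest adjusted p 0.0627); the numbers share no known pairing. Without a filter 2004 genes passed (734 higher in GP). With at least 10 counts in every library 2198 passed (971 higher in GP), and genes without counts in D91 or GP fell to 0 and 0 by construction. DESeq2, with its own filtering to 25080 genes, called 1822 (763 higher in GP, 1059 in D91). Limma on the deposited signal called 2563 (1092 higher in GP) with a pseudocount of 1, 2043 (835 and 1208) with 0.1, and 3478 (1918 and 1560) on all genes passing the filter in the deposited gene table. Against a 2-fold change 1149 passed (648 and 501). The deposited gene table gave 0 genes in edgeR (0 and 0; 6665 at an unadjusted p under 0.05) and 1607 in DESeq2 (866 and 741), of which 779 were among the 3465. With at least 50 counts in the other cultivar, 41 genes lacked counts in D91 and 35 in GP. Leaving out each library in turn gave 700 to 6902 genes, 385 to 3133 higher in GP, 315 to 3769 higher in D91, 109 to 422 without counts in D91, and 0 to 2950 isoforms. Except where stated, the cause was not tested. The 4 named genes, chosen for large folds, passed in 19 of 20 alternatives; in the deposited gene table with edgeR each had an adjusted p of 0.0947. Lists, plastid shares, chromosome windows and leaving out organelle genes were not run, since no gene has a name. In the simulation, with 200 of 18035 genes changed and the same dispersion in both cultivars, 5% of 2-fold changes were recovered. The data had calls at 19.2% of genes and so a less strict cutoff, and their recovery was not measured. What limits recovery was not separated.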

Other observations

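Genes of one locus of the assembly mostly differed in the same direction. The 1652 genes higher in GP lay at 1519 loci and the 1813 genes higher in D91 at 1717, and 6 loci held both. Most of these loci held a single such gene and could not hold both. Over 1704 loci with several tested genes, the log2 fold changes of the first 2 genes correlated across loci at r = 0.73, against a highest value of 0.07 in 1000 random pairings (permutation p = 0.001, one-sided, the smallest these can give). Genes under the same locus number may share reads or belong to the same transcript, which random pairings across loci leave out. The p-value therefore does not show that separate genes changed together. Calls also gathered along the locus numbers. In windows of 25 consecutive loci the sum of squared net calls was 1.37 times the random mean, and that of loci with a gene lacking counts in one cultivar was 1.41 times (permutation p = 0.001 for each, one-sided, the smallest 1000 permutations can give). The largest window held 9 such loci. In windows of 100 loci these ratios were 1.56 and 1.29. Some genes at different locus numbers had the same counts in all 4 libraries, as reads shared between copies would give. Without the 537 loci holding such genes, the ratios were 1.28 and 1.34 in windows of 25 loci and 1.46 and 1.29 in windows of 100 (permutation p = 0.001 for each, one-sided), and r within loci was 0.74. Copies that differ slightly in counts were not removed, so the loci are not all independent. What the order of the numbers stands for is not given in the sources used here.

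The tests on genes without counts, on loci, on locus order and by limma on all genes of the deposited gene table were chosen after the results were seen, and the other tests on the deposited gene table and those on the D91 replicates were chosen after those patterns but before their own outcomes. The comparison of direction between abundance classes and the shuffle of isoform directions were also not fixed in advance.

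The 225 and 143 genes without counts in one cultivar lay at 349 loci, and no locus held both kinds (0). Most of these loci held a single such gene and could not hold both kinds. Alleles of the cultivars assembled as separate genes of one locus may give genes without counts in one cultivar, and summing the locus would then end the call. At 315 loci no other gene was tested, so summing had little to add there and does not decide. At 273 of these 315 loci, no gene of the locus had any count in the cultivar without counts. A separate allele at the same locus number would have carried counts there. This argues against that explanation at the 273 loci. The 34 loci with other tested genes were not counted in this way. Taking loci without another tested gene favours such an outcome, so the share of 273 says nothing about the 349 loci as a set. Of the 34 loci with other tested genes, 23 (67.6%) stayed past the threshold in the same direction, between the bounds of 50% and 80%. The other genes at these loci were 53, of which 39.6% were called in the same direction and 7, at 4 loci, in the opposite direction, and none of these 4 loci (0) stayed past the threshold after summing. Sequence differences that keep the reads of one cultivar from being assigned may also empty a gene, and the median log2 difference of the 53 genes was 0.62 toward the cultivar with counts, between the bounds of 0.5 and 1. Outside the 273 loci, separate alleles at one locus number stay open. At all 349 loci, separate alleles at different locus numbers (not tested), failed assignment and a real difference in expression or gene content stay open. They cannot be told apart without the transcript sequences.

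The deposited gene table gave no gene past the threshold in edgeR (0 of 27462, smallest adjusted p 0.0947), where the summed counts gave 3465. Limited to the 18035 genes tested on summed counts, the same scaled values gave 2694 genes in edgeR. This is consistent with features of few reads, which scaled values let past the filter, raising the estimated spread. If a count model did not suit these values, limma was expected to call at least 0.5 times as many genes as 3465. It called 2563 of the same 18035 genes on the deposited TMM-scaled values, and 3478 of all 27462, of which 1348 were among the 3465. DESeq2, also a count model, called 1607 genes in the unrestricted table, 779 of them among the 3465, and edgeR called genes once the set was limited, so the 0 was not common to count models, and the model as fitted by edgeR to all genes stays open as a part of the cause. Which of the deposited tables the study tested is not known here.

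The D91 replicates differed more than the GP replicates, with biological coefficients of variation of 0.268 and 0.114 and 1881 against 830 genes apart by over 2-fold. D91 replicate 2 was the deepest library, and thinning it to the total of replicate 1 left the D91 value at 0.263. This coefficient already allows for counting noise, so thinning could hardly move it and does not decide. The chi-square between replicates keeps counting noise. It was 9.07 per gene in D91, 7.79 after thinning and 2.21 in GP, which argues against unequal depth as the main cause. Removing a smooth trend with transcript length left the coefficient at 0.265 in D91 and 0.115 in GP, which argues against such a trend. A difference between cultures, preparation or a larger variability of D91 callus stays open and was not tested, with 1 pair of libraries per cultivar.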
